A study of Homo sapiens with 6 samples.

How the data were processed

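Total RNA from SH-SY5Y cells was treated with DNase, made into stranded libraries with a kit for mRNA, size-selected after PCR and sequenced as paired 150 nt reads on an Illumina NovaSeq instrument, per the labels' protocols. Reads were aligned to GRCh38, and HISAT2 and DESeq2 were used, per the submitters' processing notes, which give no versions. The counting tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share sequence with a paralog or pseudogene, and genes that overlap, are therefore uncertain to the extent that reads could be split between or withheld from them.

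The deposited count table holds whole-number read counts per gene for the 6 libraries, without normalization, for 28862 genes. The deposited FPKM table holds values scaled by gene length and library depth for 28501 genes, rounded to 2 decimals. Samples were grouped by their titles and matched to columns by name, giving 3 control plasmid libraries and 3 libraries labelled SMN1 overexpression. Totals of 30379242 to 40275498 reads per library set the precision: 3 reads, the 95% upper limit on the expected count where 0 reads are seen, correspond to 0.0745 to 0.0988 CPM. Within each group every pair of libraries differed by more than counting noise (chi-square per degree of freedom 2.52 to 4.41, against 60.1 to 68.7 between groups), so no pair was treated as 1 library deposited a second time. Repeat preparations of 1 culture would also differ by more than counting noise, so this does not show that the cultures were separate.

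Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: TMM factors, the default filterByExpr filter, a quasi-likelihood fit with the group as the only term, a two-sided test and Benjamini-Hochberg adjustment, with calls at an adjusted p of at most 0.05. Standard errors are the absolute log2 fold change over the square root of F. The count of genes changed at least 2-fold is a filter on the fitted fold, not a test against it. SMN1 and SMN2 were also tested as 1 summed row. The 32 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, leaving out SMN1 and SMN2. Of the 1225 list entries 1164 were found in the table, older symbols included, and members removed by the filter were not tested. The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined, apart from the additions named here.

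The genes named are SMN1 and SMN2, GEMIN2, DDX20 and GEMIN5. To these come the 10 genes with the largest and the 10 with the smallest fold change among those called, at 5 CPM or more in a group, without overlap between groups and with a gene symbol. From each list that passed or had at least 3 called members come up to 3 called members in order of p. Any other gene is said to have been named after its value was seen. Some genes that the rule names are not reported here.

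Gene lengths, GC content and coordinates were taken from GENCODE v29 on GRCh38, matched by Ensembl identifier without its version: 28038 of 28862 listed genes and 15663 of 15829 tested genes had values. Length is that of all annotated exons of a gene joined, and GC content is that of its longest annotated transcript. The steps were tested on simulated counts for 15638 genes with the means and library sizes of these samples. The gene test recovered 81.8% of genes changed 1.5-fold, 89.2% of those changed 2-fold and 100% of those changed 4-fold, and called 7 of 15446 unchanged genes. Counts were drawn gene by gene from the dispersions fitted to these data, with most genes unchanged and no length or GC trend. The rate of false calls under differences as broad as those found here was therefore not tested.

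The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, library sizes without SMN1 and SMN2, no filter and a stricter filter (1 CPM in at least 3 libraries), the replicate number as a block, leaving out each library, limma on log2(FPKM + 0.1) or log2(FPKM + 1) for genes at 0.5 FPKM or more, the latter also without the filter, glmTreat against a 2-fold change, a 1.5-fold filter, camera with an estimated correlation, and fry. Fold changes on FPKM are on the log2(value + pseudocount) scale and understate changes of low genes. A correction for gene length and GC content by splines within each library, removal of the ribosomal protein and mitochondrial genome genes from the counts (leaving 15731 genes tested), and thinning to the smallest library were added after seeing the data.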

Results

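Messenger RNA was sequenced from SH-SY5Y cells, a human neuroblastoma line of adrenergic, neuron-like character that is widely used as a model of peripheral and catecholaminergic neurons. The series asks how the transcriptome changes when SMN1 is overexpressed, with neuropathic pain as its stated background. It holds 6 libraries in 2 groups: 3 from cells given a control plasmid and 3 labelled SMN1 overexpression. The control libraries held 30827766, 31286361 and 30379242 reads assigned to genes. The libraries labelled SMN1 overexpression, called here the SMN1-labelled libraries, held 32664151, 40275498 and 31740870. Of the 28862 genes listed, 15829 passed the filter on low counts and were tested. Levels are given in CPM, read counts relative to a library size scaled by TMM factors, as mean ± SD over n = 3 libraries, and every fold is the SMN1-labelled group relative to the control group. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

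SMN1 itself was not higher in the SMN1-labelled libraries. SMN1 encodes the survival motor neuron protein, the core of a complex that loads Sm proteins onto small nuclear RNAs, and its loss causes spinal muscular atrophy. It was at 20.02 ± 0.432 CPM in the control libraries and 16 ± 1.08 CPM in the SMN1-labelled libraries, 1.25-fold lower (log2 fold change -0.32, SE 0.06, edgeR quasi-likelihood adjusted p = 9.40e-05). Its reads numbered 602, 624 and 568 in the control libraries and 494, 691 and 547 in the SMN1-labelled ones, and after scaling every SMN1-labelled library lay below every control library. SMN2, the near-identical paralog, went the same way, from 9.40 ± 0.358 to 7.63 ± 0.427 CPM (log2 fold change -0.30, SE 0.08, edgeR adjusted p = 0.0031), and was no longer past the threshold on log2(FPKM + 1) without a filter (limma adjusted p = 0.0546, against 0.000362 to 0.0207 over the other alternatives). The label of these 3 libraries and the level of the gene named in it therefore point in different directions, and every direction that follows is between libraries as labelled.

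The genes lie on the plus strand of chromosome 5 in GRCh38, SMN1 at 70925030 to 70953942 and SMN2 at 70049612 to 70078522 in the GENCODE v29 annotation. Their coding sequences are 885 nt long and differ at 1 base, so the split of reads between them is uncertain. Of the 736 windows of 150 nt, the read length, in the SMN1 coding sequence, 46 (6.25%) do not occur in an annotated SMN2 transcript. In the annotated SMN1 transcript of 1536 nt, 300 of 1387 windows (21.6%) do not. With the reads of both genes summed, the level was 29.4 ± 0.780 CPM in the control libraries and 23.6 ± 1.51 CPM in the SMN1-labelled libraries, a log2 fold change of -0.32 (95% interval -0.43 to -0.20, edgeR adjusted p = 2.23e-05). SMN1 took 68.0% of the summed reads in the control group (1794 of 2637, 95% Wilson interval 66.2 to 69.8) and 67.7% in the SMN1-labelled group (1732 of 2557, 65.9 to 69.5). The difference of -0.296 percentage points had a 95% interval of -2.84 to 2.24 and did not pass Fisher's exact test, two-sided (p = 0.835). These intervals cover counting error only.

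**Figure D1:**
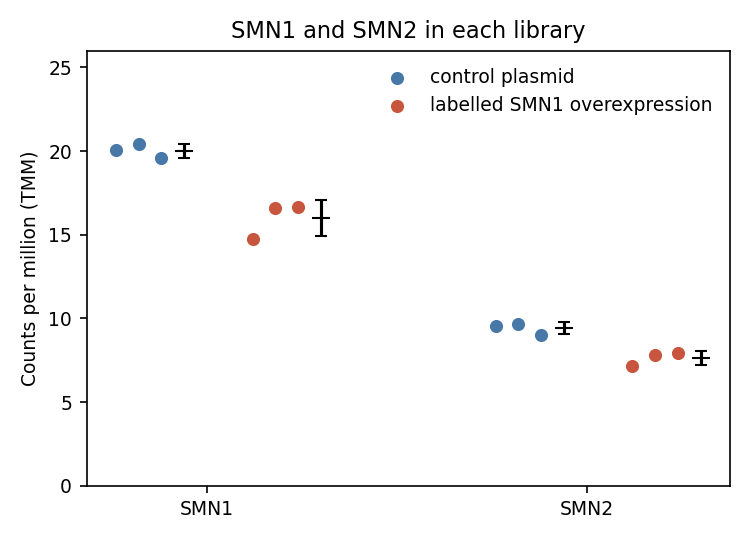
CPM of SMN1 and SMN2 in each of the 6 libraries (points), with the group mean and SD (n = 3) in black beside them. SMN1 lay at 20.02 ± 0.432 in the control libraries and 16 ± 1.08 in the SMN1-labelled libraries, and both genes were lower in all 3 SMN1-labelled libraries than in any control library.

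The groups nevertheless differed across the transcriptome. In the SMN1-labelled libraries 4426 genes were higher and 4466 lower than in the control libraries (edgeR adjusted p at most 0.05), together 56.2% of the genes tested. Most of these differences were small: 78.5% of the called genes changed by under 1.5-fold, and the median fold of a called gene was 1.295. At 2-fold or more, 115 genes were higher and 354 lower. Of 1636 long non-coding RNA genes tested 158 rose and 395 fell, and of 13201 protein-coding genes 4162 rose and 3856 fell. For 9603 genes (60.7%) the libraries of the groups did not overlap, against the 10% that chance gives with 3 against 3. Libraries within a group were close, with a common biological coefficient of variation of 0.0343, and the first principal component (65.2% of the variance) separated the groups. On the deposited FPKM values, whose sums were 310427 ± 2911 in the control and 279882 ± 493 in the SMN1-labelled libraries, 62.5% of the calls were higher, against 49.8% on the counts.

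Among called genes at 5 CPM or more in a group whose groups did not overlap, CBLN4 and NEUROG2 had the largest increases in the SMN1-labelled libraries and FOSB and FOS the largest decreases. CBLN4, a secreted synaptic organiser of the cerebellin family, rose 4.06-fold, from 13.6 ± 0.444 to 55.1 ± 1.13 CPM. NEUROG2, a proneural transcription factor, rose 3.67-fold, from 56.8 ± 2.27 to 208 ± 9.61 CPM. The laminin subunit gene LAMA3 rose 3.04-fold, PHLDA1 2.94-fold, NYAP2 2.93-fold, ANKRD1 2.92-fold, the somatostatin receptor gene SSTR2 2.89-fold and ARHGAP36 2.86-fold (153 ± 5.21 to 438 ± 12.9 CPM). VSNL1, which encodes a neuronal calcium sensor, rose 2.66-fold, and CNTNAP4 2.64-fold. FOSB and FOS encode transcription factors that cells induce on stimulation. FOSB fell 12.6-fold, from 7.37 ± 0.622 to 0.582 ± 0.0675 CPM, and FOS fell 10.6-fold, from 51.2 ± 0.676 to 4.85 ± 0.290 CPM. The glycoprotein gene GPNMB was 5.74-fold lower, the procollagen protease gene ADAMTS2 5.45-fold, GNG8 4.29-fold, PDZRN3 4.26-fold, the extracellular matrix gene TNR 3.85-fold, BFSP1 3.43-fold and EGR1 3.27-fold. RET, the receptor tyrosine kinase for ligands of the GDNF family, fell 3.95-fold, from 49.4 ± 0.709 to 12.5 ± 0.296 CPM. Over these 20 genes the edgeR adjusted p ranged from 2.89e-22 for FOS to 1.71e-09 for CNTNAP4.

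**Figure D2:**
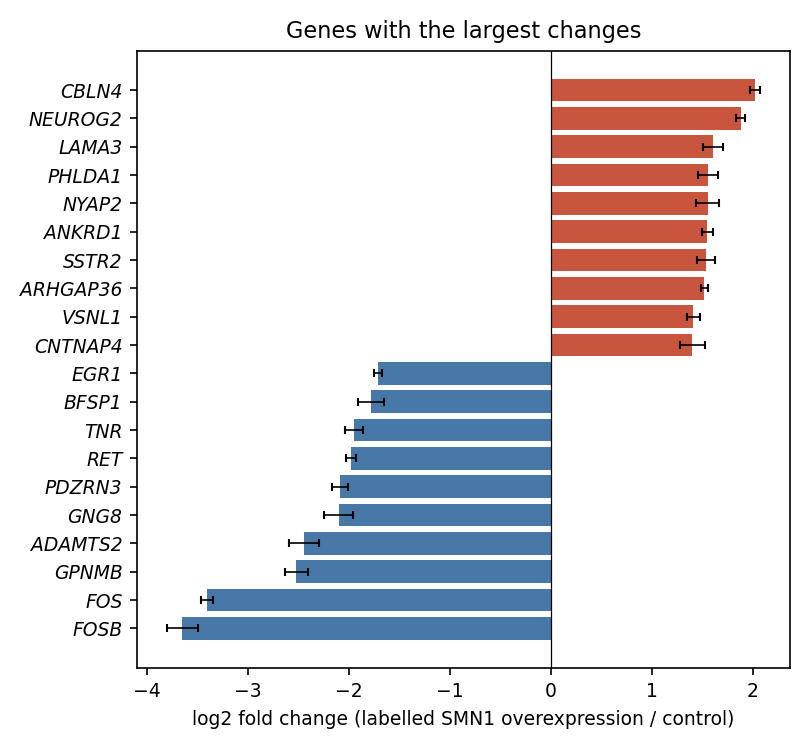
The 10 genes with the largest and the 10 with the smallest log2 fold change (bars, SMN1-labelled libraries relative to control, with standard errors) among genes past the threshold, at 5 CPM or more in a group and without overlap between groups. CBLN4 stands at 2.02 and FOSB at -3.65.

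The gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 32 lists. In the SMN1-labelled libraries 3 lists were higher and 12 lower. No list passed when the correlation was estimated from these 6 libraries: the smallest adjusted p was 0.0827, 7 lists had an unadjusted p under 0.05, and the 15 lists that passed at the preset value had adjusted p up to 0.222. The competitive list results therefore rest on the preset correlation. The rotation test fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 8 lists higher and 21 lower. It counts among the alternatives in the ranges given for lists, so their lowest values can be those of fry and not of camera. Counts of list members that rose or fell are calls over all genes tested. They were the same adjusted over the list alone unless another count is given.

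The partners of SMN moved both ways. Of the 8 tested members of the SMN complex list, 4 rose and 4 fell in the SMN1-labelled libraries, and the list did not pass (camera adjusted p = 0.879). DDX20, which encodes the helicase Gemin3, rose 1.26-fold (13.2 ± 0.281 to 16.6 ± 0.162 CPM, edgeR adjusted p = 6.67e-05). GEMIN5, whose product binds small nuclear RNAs, rose 1.11-fold (edgeR adjusted p = 0.0142), a call lost with DESeq2 (adjusted p = 0.0565). GEMIN2, whose product holds Sm proteins during ring assembly, stood at 2.69 ± 0.233 and 3.44 ± 0.719 CPM (log2 fold change 0.37, SE 0.15, edgeR adjusted p = 0.0389). That call did not hold without the second SMN1-labelled library, where the log2 fold change was 0.18 (edgeR adjusted p = 0.359), or without the first, the second or the third control library (0.0587, 0.141 and 0.0503). It was also lost with DESeq2 (0.102), with limma-voom (0.0518), on log2(FPKM + 1) without a filter (0.136) and after a correction for gene length and GC content (0.0917), within 0.00754 to 0.359 over the alternatives. DDX20 and GEMIN5 were no longer past the threshold after that correction either (adjusted p = 0.133 and 0.335, the highest over their alternatives, with 3.24e-06 and 0.0012 the lowest). GEMIN6 fell 1.13-fold and GEMIN8 1.16-fold, and GEMIN8 was not called on FPKM values or after that correction (adjusted p from 0.000597 to 0.201 over the alternatives). GEMIN6 was not called on log2(FPKM + 1) without a filter (limma adjusted p = 0.0509, within 1.82e-06 to 0.0509 over the alternatives). After the correction 1 of the 8 members was higher and 1 lower.

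Genes for Sm proteins, which the SMN complex loads onto small nuclear RNAs, and for LSm proteins were mostly lower in the SMN1-labelled libraries. In the list of Sm and LSm proteins and their assembly factors, 18 of 27 tested members fell and 3 rose (4 adjusted over the list alone), with a median log2 fold change of -0.23 (camera adjusted p = 0.0029, adjusted p = 0.201 with an estimated correlation). SNRPF fell 1.58-fold (274 ± 6.46 to 174 ± 3.75 CPM), SNRPD1 1.42-fold and LSM4 1.48-fold. The list did not pass after the length and GC correction (camera adjusted p = 0.0646, within 0.000104 to 0.201 over the alternatives), which took its median to -0.08. Among 49 spliceosome and splicing factor genes 31 fell and 9 rose (camera adjusted p = 0.003, adjusted p = 0.222 with an estimated correlation). The U1 components SNRPA and SNRNP70 fell 1.73-fold and 1.53-fold, SNRNP70 from 915 ± 12.3 to 597 ± 12.2 CPM, and the U2 component SF3A2 fell 1.43-fold. Of 10 genes of the minor spliceosome, which removes a rare class of introns, 4 fell, SCNM1, SNRNP35 and ZMAT5 among them by 1.51-, 1.44- and 1.37-fold, and 2 rose. The list did not pass (camera adjusted p = 0.40), though fry called it lower (adjusted p = 0.000572, within 0.000572 to 0.604 over the alternatives). Reported modifiers of spinal muscular atrophy also split, with 8 of 18 higher (9 adjusted over the list alone) and 4 lower (camera adjusted p = 0.498). The microtubule regulator STMN1 fell 1.58-fold (4110 ± 63.5 to 2605 ± 73.3 CPM) and the actin-binding profilin PFN1 1.56-fold, whereas the neuronal profilin PFN2 rose 1.28-fold.

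Genes of the unfolded protein response, many of them endoplasmic reticulum chaperones, were higher in the SMN1-labelled libraries. Of 26 tested, 22 rose (23 adjusted over the list alone) and 1 fell, with a median log2 fold change of 0.43 (camera adjusted p = 5.63e-08, adjusted p = 0.0827 with an estimated correlation). HSP90B1, the endoplasmic reticulum form of HSP90, rose 1.73-fold from 1799 ± 38.1 to 3106 ± 8.17 CPM, the lectin chaperone calnexin (CANX) 1.64-fold, and HSPA5, which encodes BiP, 1.53-fold. The 1 member that fell was SEC61B, a subunit of the translocation channel, with a log2 fold change of -0.22; it was named after its value was seen. Of 22 heat shock genes 11 rose and 5 fell (6 adjusted over the list alone). The cytosolic chaperones HSP90AA1, HSPH1 and HSPA4L rose 1.42-, 1.43- and 1.56-fold, but the list did not pass (camera adjusted p = 0.166). It passed after the length and GC correction (camera adjusted p = 0.0147), with DESeq2 and without a filter on low counts, within 0.0029 to 0.492 over the alternatives.

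The integrated stress response, which shares the kinase PERK with the unfolded protein response, went the other way. Of its 27 tested genes 16 fell and 2 rose in the SMN1-labelled libraries (camera adjusted p = 0.0013, adjusted p = 0.0877 with an estimated correlation). The regulator ATF4 fell 1.43-fold (269 ± 6.83 to 188 ± 2.18 CPM), PPP1R15A, the phosphatase subunit that acts on eIF2, 1.57-fold, and the serine synthesis gene PHGDH 1.43-fold. The p53 target list was higher, with 15 of 29 members up and 2 down (camera adjusted p = 0.000843, adjusted p = 0.0877 with an estimated correlation). SESN1, a stress-induced inhibitor of mTORC1, rose 1.93-fold from 10.7 ± 0.0369 to 20.6 ± 1.15 CPM, TP53INP1 1.79-fold and ZMAT3 1.72-fold. The targets that fell were TP53I3 (log2 fold change -0.58) and CMBL (-0.12), both named after their values were seen.

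Cell cycle genes were lower in the SMN1-labelled libraries. In the list for the G1/S transition and DNA replication, 30 of 42 genes fell and 1 rose (camera adjusted p = 6.59e-07, adjusted p = 0.0877 with an estimated correlation). The replicative helicase subunit MCM5 fell 1.66-fold (179 ± 1.40 to 108 ± 3.08 CPM), the flap endonuclease FEN1 1.51-fold and the licensing factor CDT1 1.70-fold. The gene that rose was CCND1, encoding cyclin D1 (log2 fold change 0.23), named after its value was seen. Of 47 genes of G2/M and mitosis 29 fell and 4 rose (camera adjusted p = 0.000103, adjusted p = 0.201 with an estimated correlation). UBE2C fell 2.09-fold from 102 ± 3.57 to 49.2 ± 8.40 CPM, and AURKB and PTTG1 fell 1.71- and 1.70-fold. Of 14 replication-dependent histone genes 7 fell, H1-2 by 3.10-fold (22.9 ± 0.501 to 7.35 ± 0.906 CPM), H2BC9 by 2.12-fold and H2BC12 by 1.46-fold (camera adjusted p = 0.0225, adjusted p = 0.201 with an estimated correlation). The histone list lost its call without the first or the second control library (camera adjusted p = 0.0711 and 0.0526), with DESeq2 (0.0609) and after the length and GC correction (0.0655), within 0.000326 to 0.201 over the alternatives. H2BC12 also lost its call after that correction (log2 fold change -0.12, edgeR adjusted p = 0.378, within 5.03e-06 to 0.378 over the alternatives). Most replication-dependent histone mRNAs carry no poly(A) tail, and whether the library kit selected poly(A) RNA is not given in the sources used here.

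Genes of the ribosome and of the respiratory chain were lower in the SMN1-labelled libraries. Of 75 cytosolic ribosomal protein genes 71 fell (72 adjusted over the list alone) and the other 4 did not pass, with a median log2 fold change of -0.40 (camera adjusted p = 3.54e-17, adjusted p = 0.0827 with an estimated correlation). RPL35 fell 1.58-fold (1004 ± 1.15 to 634 ± 17.5 CPM), RPS26 1.65-fold and RPL28 1.55-fold. Ribosomal protein genes have many processed pseudogenes, with which reads could be shared. Their summed share of all reads was 6.15% ± 0.0798 in the control libraries and 5.01% ± 0.0177 in the SMN1-labelled libraries. Of 67 nuclear-encoded oxidative phosphorylation genes 54 fell (55 adjusted over the list alone) and 1 rose (camera adjusted p = 2.58e-11, adjusted p = 0.113 with an estimated correlation). The complex I subunits NDUFB7 and NDUFB10 fell 1.73- and 1.50-fold and cytochrome c1 (CYC1) 1.64-fold. All 13 mitochondrially encoded mRNAs fell, with a median log2 fold change of -0.58 (camera adjusted p = 7.94e-07, adjusted p = 0.201 with an estimated correlation). MT-ND2 fell 1.63-fold (6232 ± 331 to 3820 ± 160 CPM), MT-CO2 1.50-fold and MT-CO3 1.53-fold. The mitochondrial genome supplied 6.18% ± 0.209 of reads in the control libraries and 4.85% ± 0.0575 in the SMN1-labelled ones. No library of one group overlapped the other in either share, and an exact permutation test of 3 against 3 cannot go below p = 0.1.

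Short and GC-rich genes as a class were lower in the SMN1-labelled libraries, which bears on these lists of short genes. Across 15663 genes, which are not independent replicates, the log2 fold change correlated with exonic gene length (Spearman's rho 0.34) and with GC content (rho -0.43). In the shortest decile of genes, with a median length of 871 nt, the median log2 fold change was -0.26, and in the longest decile, with a median of 12610 nt, it was 0.15. After removal of the trends within each library, 4087 genes were higher and 3602 lower. Of the 8892 original calls 5897 kept their call and direction, and for 745 the fitted change had the opposite sign, whether or not it was called.

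**Figure D3:**
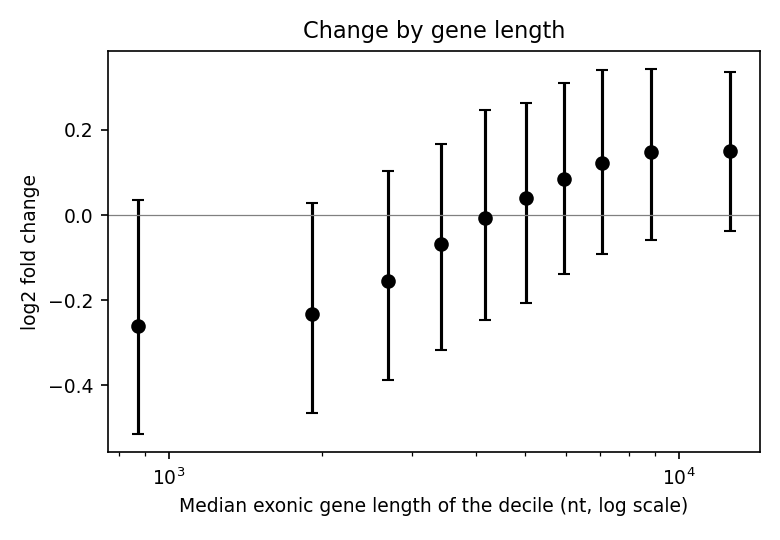
Median log2 fold change (points, SMN1-labelled libraries relative to control; bars, the 25th to 75th percentile) in deciles of the tested genes by exonic length, on a log axis in nt. The median ran from -0.26 in the shortest decile to 0.15 in the longest.

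Other metabolic lists did not pass. Of 34 glycolysis and hypoxia genes 14 fell and 7 rose in the SMN1-labelled libraries (camera adjusted p = 0.457). The glycolytic enzyme genes GAPDH, ENO2 and PGAM1 fell 1.65-, 1.38- and 1.31-fold, GAPDH from 2011 ± 45.5 to 1222 ± 21.7 CPM. Cholesterol synthesis genes were balanced at 7 up and 7 down of 24, with FDPS and EBP down 1.49-fold each and CYP51A1 up 1.48-fold (camera adjusted p = 0.941, with a median log2 fold change of 0.03, a mean of -0.01 and a downward test direction). Among 31 autophagy and lysosome genes 13 fell and 7 rose (camera adjusted p = 0.498). Those that fell included the cathepsin CTSB, the progranulin gene GRN and NPC2, by 1.34-, 1.37- and 1.61-fold. Of 26 NRF2 and oxidative stress genes 14 fell and 7 rose (camera adjusted p = 0.102), with the metallothionein MT2A down 1.92-fold, the quinone reductase NQO1 2.26-fold and the ferritin heavy chain FTH1 1.39-fold. That list passed with DESeq2 (camera adjusted p = 0.00155) and without a filter on low counts (0.0433), within 0.000326 to 0.319 over the alternatives.

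Immediate early genes, which cells induce within minutes of a stimulus, were lower in the SMN1-labelled libraries. Of 25 tested 15 fell (17 adjusted over the list alone) and 5 rose, with a median log2 fold change of -0.51 (camera adjusted p = 0.000709, adjusted p = 0.0877 with an estimated correlation). The length and GC correction took that median to -0.27, and the list still passed (camera adjusted p = 0.000862). FOS, FOSB and EGR1 led the list. The members that rose were DUSP4 (log2 fold change 0.62), CCN2 (0.62), SRF (0.31), KLF10 (0.31) and MYC (0.15), all named after their values were seen. Inflammatory genes of the NF-kB list fell in 11 of 24 cases (12 adjusted over the list alone) and rose in 4, short of the threshold (camera adjusted p = 0.0559). NFKBIA, the inhibitor that NF-kB itself induces, fell 1.77-fold (52.6 ± 1.21 to 29.8 ± 0.632 CPM), HMGB1 1.52-fold and the chemokine gene CCL2 4.55-fold from a low level (3.26 ± 0.266 to 0.717 ± 0.0644 CPM). The list passed with DESeq2 (camera adjusted p = 0.0387), on FPKM values, without a filter on low counts and without the third SMN1-labelled library (0.0306), within 0.000239 to 0.209 over the alternatives. Interferon-stimulated genes showed no common direction, with 5 of 21 up and 4 down (camera adjusted p = 0.913). OAS1 and IRF7 fell 1.58- and 1.85-fold.

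SH-SY5Y cultures can hold both adrenergic, neuroblast-like cells and substrate-adherent mesenchymal cells, whose markers were tested as separate lists. Of 34 adrenergic identity genes 21 rose (22 adjusted over the list alone) and 11 fell in the SMN1-labelled libraries (camera adjusted p = 0.0455, adjusted p = 0.201 with an estimated correlation). CHGB, a granin of secretory vesicles, rose 1.73-fold from 7761 ± 243 to 13386 ± 97.2 CPM and the nicotinic receptor subunit CHRNA3 1.66-fold, but RET, on the same list, fell. The adrenergic call was close to the threshold and was lost without the second or the third control library or the first SMN1-labelled library (camera adjusted p = 0.0518, 0.0562 and 0.0778), with a stricter filter (0.10), on filtered FPKM values, without ribosomal protein and mitochondrial genes (0.0538) and after thinning to the smallest library (0.0532), within 0.000399 to 0.201 over the alternatives. After the length and GC correction the adrenergic list passed at the lowest of these values (camera adjusted p = 0.000399), with 23 members higher and 4 lower. Of 43 mesenchymal markers 24 fell and 9 rose, with a median log2 fold change of -0.33 (camera adjusted p = 0.000843, adjusted p = 0.201 with an estimated correlation). The collagens COL1A1 and COL3A1 fell 2.94-fold (21.7 ± 1.33 to 7.44 ± 1.28 CPM) and 2.58-fold, and vimentin (VIM) fell 2.04-fold (189 ± 3.25 to 92.6 ± 1.49 CPM). Of 6 Schwann and glial markers 5 fell (camera adjusted p = 0.0268, adjusted p = 0.201 with an estimated correlation). NES, an intermediate filament gene of neural progenitors, fell 1.31-fold (1854 ± 26 to 1415 ± 17.8 CPM), S100B 2.34-fold and EGR2 2.88-fold, the last from 0.647 ± 0.0763 CPM. Without the third control library that small list did not pass (camera adjusted p = 0.0688, within 0.00117 to 0.201 over the alternatives).

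**Figure D4:**
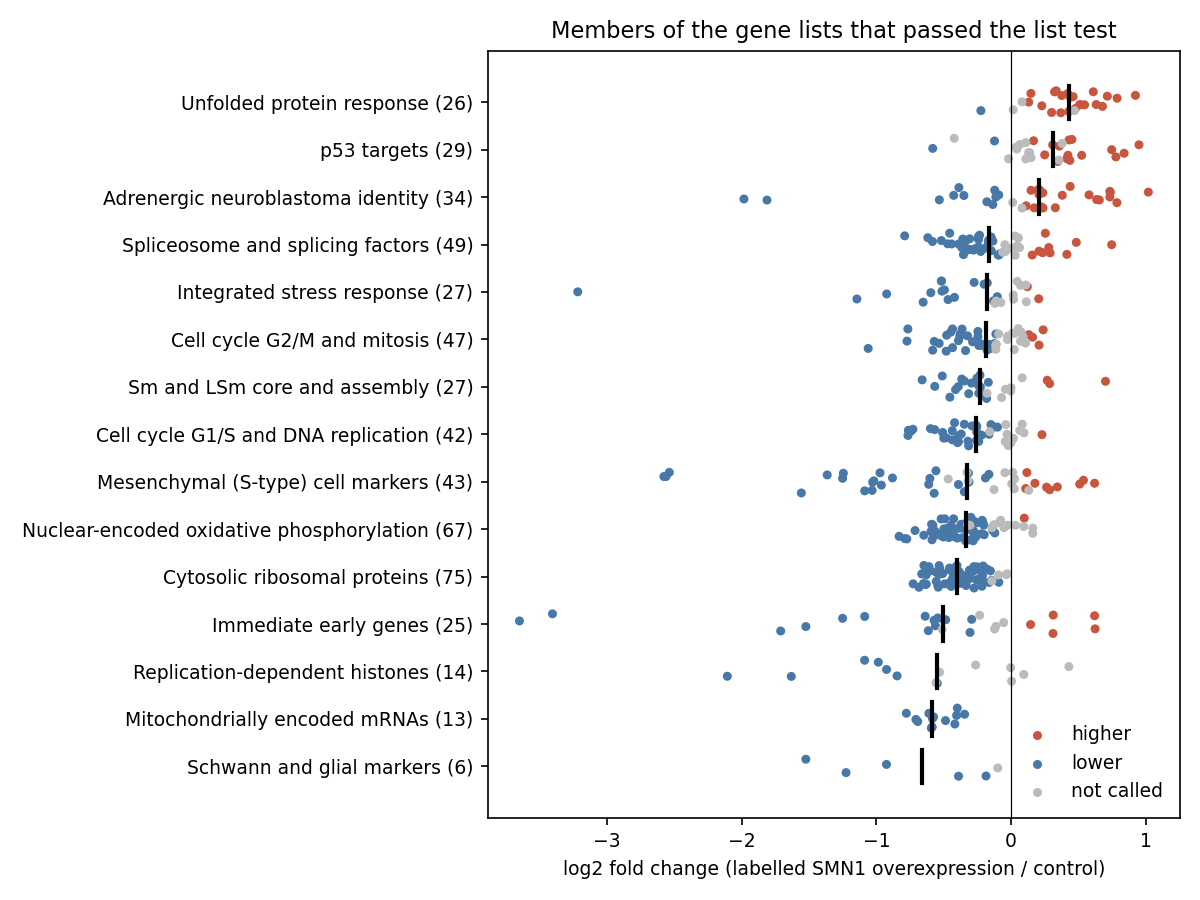
Log2 fold change (SMN1-labelled libraries relative to control) of each tested member of the 15 lists that passed at the preset correlation, with the number of members in brackets and the median as a black line. Members called higher are red, those called lower blue and those not called grey, and points are spread vertically for legibility. The median ran from 0.43 for the unfolded protein response to -0.66 for the Schwann and glial markers.

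In the lists of genes tied to pain, the background of the study, members changed in both directions and no list passed camera. With fry the ion channel and the glutamate, GABA and glycine lists were called higher (adjusted p = 0.0021 and 0.000572), and the neuropeptide and neurotrophin lists lower (0.0276 and 0.00187). Of 38 tested ion channel genes linked to pain 17 rose and 11 fell in the SMN1-labelled libraries (camera adjusted p = 0.40). SCN3B, an auxiliary subunit of sodium channels, rose 1.31-fold (25.1 ± 0.502 to 32.9 ± 0.819 CPM), while the sodium-activated potassium channel KCNT1 and the T-type calcium channel CACNA1G fell 1.92- and 2.08-fold. SCN9A, the sodium channel gene of inherited pain disorders, did not pass (log2 fold change 0.12) and was named after its value was seen. Of 19 neuropeptide, opioid and pain receptor genes 8 fell and 5 rose (camera adjusted p = 0.691). GAL, encoding the neuropeptide galanin, fell 2.57-fold from 39.8 ± 1.82 to 15.5 ± 1.08 CPM, whereas SSTR2 rose as above and the thrombin receptor F2R rose 1.57-fold. Neurotrophin and receptor genes were divided at 10 up and 11 down of 26 (camera adjusted p = 0.892). The growth factor gene IGF2, which overlaps the readthrough gene INS-IGF2, rose 2.28-fold from 6529 ± 205 to 14905 ± 581 CPM, and pleiotrophin (PTN) fell 1.84-fold alongside RET. Of 27 glutamate, GABA and glycine signalling genes 13 rose (14 adjusted over the list alone) and 6 fell, just short of the threshold (camera adjusted p = 0.0599). The metabotropic receptor GRM8 rose 1.78-fold. Without the third control or the third SMN1-labelled library that list passed (camera adjusted p = 0.0364 and 0.0306), as it did on filtered FPKM values and without a filter on counts, within 0.000572 to 0.270 over the alternatives.

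Neuronal structural genes likewise moved in both directions. Among 42 synaptic vesicle and presynaptic genes 16 rose and 11 fell in the SMN1-labelled libraries (17 and 12 adjusted over the list alone; camera adjusted p = 0.416). The active zone gene RIMBP2 and the calcium sensor SYT1 rose 1.33- and 1.34-fold and the granin SCG2 fell 1.37-fold. In the list of axon, cytoskeleton and neuronal differentiation genes 15 of 46 rose and 18 fell (19 adjusted over the list alone; camera adjusted p = 0.506). STMN4 fell 1.76-fold, and the neuronal tubulin gene TUBA1A fell 1.64-fold from 2604 ± 69.1 to 1584 ± 75.5 CPM. The axon list passed with DESeq2 (camera adjusted p = 0.0468, within 0.00176 to 0.998 over the alternatives). Axon guidance genes were even, with 13 of 43 up and 12 down (camera adjusted p = 0.561). The receptor ROBO2 and the bone morphogenetic protein co-receptor RGMB rose 1.62- and 1.70-fold, and the semaphorin receptor PLXNA2 fell 2.27-fold.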

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

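The SMN1 decrease in the libraries labelled SMN1 overexpression kept its direction and stayed past the threshold under every alternative run (log2 fold change -0.40 to -0.20), and so did that of SMN1 and SMN2 summed (-0.34 to -0.20), which was not run under the length and GC correction. The correction for length and GC content, the removal of ribosomal protein and mitochondrial genome genes, and the thinning were chosen after the results were seen. The count of genes changed at least 2-fold, 469, moved by over 1.5 times with several choices: it was 711 without a filter on low counts and 253 with a stricter one, since these add and remove low genes. It was 175 on log2(FPKM + 0.1), 32 on log2(FPKM + 1) and 31 on log2(FPKM + 1) without a filter, which also change the test, the scaling and the genes tested; the cause was not tested. It was 76 when tested against 2-fold with glmTreat, and a filter at 1.5-fold in its place gave 1911. Genes lower numbered 2883 on log2(FPKM + 1) without a filter, against 4466; the cause was not tested. Of the calls tested on log2(FPKM + 0.1), 13 had a change of the opposite sign, whether or not it was called. The 3 lists higher became 5 without a filter, for which the cause was not tested. With an estimated correlation 0 were higher and 0 lower, by limma's camera, and with fry, which tests another hypothesis, 8 were higher and 21 lower. DESeq2 called 3827 genes higher and 3883 lower, and kept 7709 of the 8892 calls. Leaving out 1 library gave 3965 to 4335 genes higher, 4049 to 4346 lower and 523 to 570 changed at least 2-fold, and kept 7804 to 8264 of the calls. Over named genes and lists, 49 single results under 1 alternative lost a call and 33 gained one, and no called direction reversed.

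The replicate numbers did not pair the libraries: deviations from the group means of same-numbered libraries correlated by 0.00528, 0.0133 and 0.003 across genes. With the number as a block 4326 genes were higher and 4382 lower, and 8659 of the 8892 calls were kept. The calls of GEMIN2 and of the adrenergic list were lost (adjusted p = 0.0547 and 0.0672) and the NF-kB list was called (0.049).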

Other observations

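Of the tests in this part, those of the 3 added gene lists were set before their results were seen, and those of SMN1, of gene length and GC content, of the mesenchymal markers and of the other splits were chosen after. GDNF family receptors changed unequally in the libraries labelled SMN1 overexpression. Beside the fall of the shared signalling receptor RET (log2 fold change -1.98), the co-receptor genes GFRA1 and GFRA3 rose (1.68 and 0.67) and GFRA2 fell (-0.92), as did the neurotrophin receptor NTRK3 (-1.35), while BDNF rose (0.63). Among the mesenchymal markers, S100A10, TGFBI and COL6A3 fell furthest (-2.58, -2.56 and -2.54). All of these genes passed edgeR's test over all genes and were named after their values were seen. S100A10, TGFBI, COL6A3 and GFRA1 changed by more than some of the leading genes. They did not meet the rule for those, 5 CPM or more in a group without overlap, so their levels may be low.

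The 3 lists were written after the leading genes were known and left those genes out. The hypotheses were that retinoic acid response genes and outputs of ERK signalling were lower, and that YAP and TEAD targets were higher, in the libraries labelled SMN1 overexpression. None passed (camera adjusted p = 0.597 for each over the 3 lists, adjusted p = 0.595 for each with an estimated correlation). Of 12 tested retinoic acid genes 6 fell, DHRS3, PLAT and RARB furthest (log2 fold change -1.996, -1.18 and -1.09), and 4 rose, TGM2 most (0.91). Of 20 ERK output genes 5 rose and 5 fell. Of 21 YAP and TEAD targets 8 rose, NT5E and TGFB2 most (0.54 and 0.48), and 5 fell, GADD45B, IGFBP3 and AXL furthest (-1.98, -1.20 and -1.13). The members of these lists were named after their values were seen. The ERK list shared 6 of its tested genes and the YAP list 2 with lists set beforehand.

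SMN1 was 1.25-fold lower, not higher, in the libraries labelled SMN1 overexpression. Reads of an unaltered SMN1 transgene split between SMN1 and SMN2 would raise the sum of both, and its log2 change had an upper 95% limit of -0.20, which argues against that explanation. If reads shared by the genes were discarded, the few reads that tell them apart should raise the SMN1 share, but it moved by -0.296 percentage points. Its 95% interval lay on both sides of 0 and covers counting error only. A rise of more than 2.24 points lies outside it, which argues against transgene reads numerous enough for that. Fewer transgene reads cannot be told apart from none at this depth. Exchanged labels cannot be told apart either: the log2 change of SMN1 minus that of SMN2 was -0.0205, within 2 SE both by read counting (SE 0.0858) and by the smaller spread of the SMN1 to SMN2 ratio between libraries (SE 0.0193). A recoded transgene whose reads would not align to SMN1, and an absence of overexpression, stay open and may each account for the pattern; no test of either was possible on gene counts.

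Short and GC-rich genes were lower in the libraries labelled SMN1 overexpression, and after correction within each library Spearman's rho with length and GC content was 0.0263 and -0.0088. The ribosomal protein list stayed lower (camera adjusted p = 5.11e-18, median log2 fold change -0.33 after and -0.40 before, SD over members 0.18 and 0.16), as did the mitochondrially encoded mRNAs (1.25e-07, -0.43 after and -0.58 before, SD 0.14 and 0.13). This argues against the trend in annotated length and GC content as their whole cause. The annotated length joins all exons of a gene (median 3109 nt for the ribosomal protein list) and need not be that of the mRNA present. A trend with mRNA length could therefore remain in that list and was not tested. After the correction 65 of the 75 ribosomal protein genes and 13 of the 13 mitochondrially encoded mRNAs were still lower, and before it the lists had adjusted p = 0.0827 and 0.201 with an estimated correlation. The trend in annotated length and GC content is also not the whole cause of the calls, since 7689 genes, 48.6% of those tested, were called after the correction. For the shift of the Sm and LSm list as a whole a length and GC trend may suffice: the median went from -0.23 to -0.08 (SD over members 0.29 before and after) and the call ended at 0.0646 because the shift became smaller. It does not account for every member, since 12 were still called lower and 6 higher after the correction. The spliceosome and splicing factor list stayed lower at the preset correlation (camera adjusted p = 2.76e-07, median log2 fold change -0.22 after and -0.17 before). Whether the trend itself came from RNA or library preparation or from the cells stays open, since it coincides with the groups and the labels give no batch.

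Mesenchymal markers were lower in the libraries labelled SMN1 overexpression. A smaller share of mesenchymal cells in these cultures would lower their markers alike, but 9 of the 33 called markers rose, CCN2, NT5E and PDGFRA most (log2 fold change 0.62, 0.54 and 0.51, named after their values were seen), which argues against it as the whole cause. The trend in annotated length and GC content is not the whole cause, as the list stayed lower after the correction (camera adjusted p = 0.00036, with 23 members lower and 9 higher). Before the correction that list had adjusted p = 0.201 with an estimated correlation. A change of state within the cells, or a smaller mesenchymal share, alone or together with other changes, may explain the fall, and the data do not tell these apart.

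With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 4426 genes higher, 4466 lower and 469 changed at least 2-fold by edgeR, and in each case 1 of the 10 splits, the real one, gave as many. The highest count of any other split was 0 in each case, with 91 to 174 genes at an unadjusted p under 0.05. Every other split put libraries of both groups on each side, in unequal numbers. The difference between the groups therefore added to the spread within each side, which keeps genes from being called, and part of it remained between the sides. The counts of these splits, for genes and for the lists below, are thus no measure of chance, and no conclusion is drawn from them. For the lists the larger side of each other split was counted, since its direction is arbitrary. By camera at the preset correlation 8 of the 10 splits, the real one included, gave at least the 3 lists higher of the real one, and 1 of the 10 gave its 12 lists lower, with 10 as the highest of the others in both cases. The other splits, in which no gene was called by edgeR, passed 2 to 12 lists in all, against 15 in the real one.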
